A study of Caenorhabditis elegans with 2 samples.

How the data were processed

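The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of PHA-4 in whole late embryos of Caenorhabditis elegans of pooled sex. The strain, OP37, carries an unc-119 mutation and the transgene insertion wgIs37, which provides PHA-4 fused to eGFP. Per the labels, the libraries are 2 biological replicates of 1 group, from separate biosamples, with a size range of 150 to 350. There was no second group, so the replicates were compared with each other and each peak set with random positions or with its own flanks.

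The authors deposited peak lists in 2 genome builds, ce10 and ce11. For each build there is a relaxed list per replicate (peaks together with background), a relaxed list called on both replicates' alignments pooled, and a final list. The file listing names this list the optimal set by the irreproducible discovery rate (IDR) and gives the pooled and both replicate lists as its sources, but how its peaks were chosen is not given in the sources used here. Per the labels' file listing, the replicate and pooled lists used 1 control alignment in ce10 and 2 in ce11. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. Each deposited peak carries a signal value, which the authors' caller computed against the control and whose scaling between libraries is not stated. Each also carries a −log10 q-value deposited by the authors, and a summit position, which is the middle of a peak of fixed width. The deposited score column is 0 for every peak and the p-value column is −1, so neither was used. Signal was used to describe, rank or filter peaks within a list. The exception is the correlation across shared peaks, fixed before the data were examined, which compares signals between replicates. The deposited files give no read counts, so the depth of each library is unknown, and intervals cover the counting of peaks only.

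Peaks were ranked by signal within each list, and the strongest 1000 of each replicate were the main sets. Peaks were shared when they overlapped by 1 bp or more. The overlap was compared with 1000 random placements of the replicate 2 peaks within the same chromosome (one-sided permutation test, smallest possible p = 0.001). Signals of shared peaks were compared across peaks with Spearman's rho and Pearson's r, with 100000 permutations (two-sided). Summits were counted in promoter windows, from 1000 bp upstream to 500 bp downstream of any annotated start of a protein-coding transcript, against 1000 random placements (one-sided). The PHA-4 consensus TRTTKRY, on either strand, was sought within 100 bp of each summit and in windows of the same width centred 500 bp to each side, and the paired difference was tested with an exact sign-flip test (two-sided). The reversed pattern YRKTTRT and the GATA site WGATAR served as controls. The reversed pattern also matches TRTTTRT, a form of the consensus, so it is not independent of the consensus. Percentages have exact Clopper-Pearson 95% intervals. Annotation-based results used ce11 coordinates with the WBcel235 sequence and the Ensembl release 115 annotation, which are of that build. No coordinates were converted between builds, and coordinates are 1-based.

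A gene was counted as having a peak when a summit lay in its promoter window. For 12 gene lists, members with a peak were compared with all other genes of the same class by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 12 lists. The lists were pharynx, intestine, body muscle, epidermis, neuron, germline, autophagy, antioxidant, heat shock, ribosomal protein and histone genes, and short RNA genes (tRNA, snoRNA, snRNA and rRNA). The comparison class was all other protein-coding genes, or for short RNA genes all other genes that are not protein-coding. Peaks near pha-4 and unc-119, the genes carried by or rescued in the strain, were counted within 20 kb of each gene. Genes were named by a rule: every final ce11 peak, the 15 shared peaks of best mean rank, up to 10 members per list with a shared peak, pha-4 and unc-119. Other genes named, including all list members with a peak in a single replicate, were chosen after their values were seen.

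The peak sets, tests, windows, motif, gene lists and naming rule were fixed before the data were examined, as were the alternatives in the number of peaks, overlap rule, window, build, control and left-out replicate. The list test fixed then used shared peaks, with each replicate alone as an alternative. Chosen after seeing the data were the list tests per replicate on nuclear genes, list tests against random placement, tests over 175 gene families defined by symbol stem with at least 10 members, tests of the difference between the replicates, the comparison of strong with weaker replicate 1 peaks, the comparison of bound genes between replicates, the shares by rank, and results without mitochondrial peaks. A p-value from a single replicate describes that library. Nearby peaks and genes that share a window are not independent.

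Analyses were run in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with plots in Matplotlib 3.10.9 and a fixed random seed of 1. The steps were tested on simulated data. With 20 and 50 of 1000 simulated peaks planted on the other list for the replicate overlap, 32 and 58 overlaps were found, chance overlaps included, and 2 of 100 such runs with none planted had p below 0.05. For the promoter share, 200 of 1000 peaks set on transcript starts raised the count by 151 above the random mean. For the PHA-4 motif, 633 of 1000 simulated summits held a site where 635 were predicted, and with no site planted p was 0.77 by the exact sign-flip test. For the gene lists, over 19973 genes, 4 of 100 random lists had p below 0.05. Left out were the ce10 lists from every annotation-based result, since no ce10 annotation was used here.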

Results

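PHA-4 is a FoxA-type forkhead factor that specifies the pharynx, the feeding organ of the worm. Its binding sites were measured by ChIP-seq of an eGFP-tagged copy in 2 biological replicates of whole late embryos. The depth of the libraries is unknown. In ce11 the relaxed list of replicate 1 held 5607 peaks, that of replicate 2 held 1729 and the pooled list held 7768, and the authors' final list by irreproducible discovery rate held 9. In replicate 1 the authors' signal had a median of 2.995 and reached 58.8, with 196 peaks above 10. In replicate 2 it had a median of 2.32 and reached 11.03, with 1 peak above 10. That peak lay in the mitochondrial gene COX2, and the peaks ranked 2 and 4 were also mitochondrial. The strongest nuclear peak of replicate 2 had a signal of 6.43. The scaling of the signal between libraries is not stated, so these values describe each list and do not compare strength. By the authors' q-values, 5248 peaks of replicate 1, none of replicate 2 and 1330 of the pooled list had q of 0.05 or less. The smallest q in replicate 2 was 0.351. Peaks were 344 bp wide in replicate 1 and 590 bp in replicate 2.

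The 2 strongest of the 9 final peaks lay within 20 kb of pha-4 on chromosome V, on either side of it. The genes elp-1, F38A6.5 and F38A6.4 lie between pha-4 and the strongest of them. The first, at V:20778315-20778664 with a signal of 59.3, was intergenic, at −1917 bp from the start of hif-1, the hypoxia-inducible factor gene. The second, at V:20749101-20749450 with a signal of 44.7, was intergenic, at −3776 bp from the start of pha-4. The third, at III:9546042-9546391 with a signal of 29.7, lay at −41 bp from a start of unc-16, which encodes a kinesin-linked scaffold protein, and inside the non-coding gene ZK1098.13. Its summit sequence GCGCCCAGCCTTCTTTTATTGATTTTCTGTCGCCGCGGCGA holds the PHA-4 site TATTGAT, centred at −1 bp from the summit. Other final peaks lay at promoters of pld-1 and C04G6.2 (II:5092399-5092748, signal 24.3), of the ribosomal protein gene rpl-12 and lin-54 (IV:13240498-13240847, signal 23.6) and of M02D8.3 (X:8737068-8737417, signal 21.7). A peak in an intron of the kinase gene mnk-1 (II:10549341-10549690) had a signal of 21.5, and an intergenic peak nearest to W02H3.3 (X:11094037-11094386) had 24.4. The remaining peak, at M:12233-12582 with a signal of 24.4, lay in the coding sequence of the mitochondrial gene ND5.

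All 9 final peaks overlapped a peak of replicate 1, and 1 of them, at ND5, overlapped a peak of replicate 2. Their ranks in replicate 1 ran from 1 to 34, and the ND5 peak ranked 73 in replicate 2 with a signal of 3.58. With summits required to lie within 100 bp, 8 of the 9 were found in replicate 1 and 0 in replicate 2. The 9 final peaks were the 9 pooled peaks of highest signal. All 100 of the strongest 100 pooled peaks overlapped a replicate 1 peak and 5 overlapped a replicate 2 peak.

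Processed in ce10, the same libraries gave 21 final peaks, which were the 21 strongest pooled peaks of that build. The number of control alignments also differed, 1 in ce10 and 2 in ce11, so an effect of the build is not separated from one of the controls. All 21 overlapped a replicate 1 peak and 2 overlapped a replicate 2 peak. One of these was again mitochondrial (M:12226-12595 in ce10, signal 24.6), and the other, at V:20756610-20756979 in ce10, had a signal of 22.2 and ranked 5 in replicate 2. The list went down to a signal of 19.2 in ce10 and to 21.5 in ce11. The number of replicate peaks differed less, with 5611 and 1630 peaks in ce10.

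**Figure D1:**
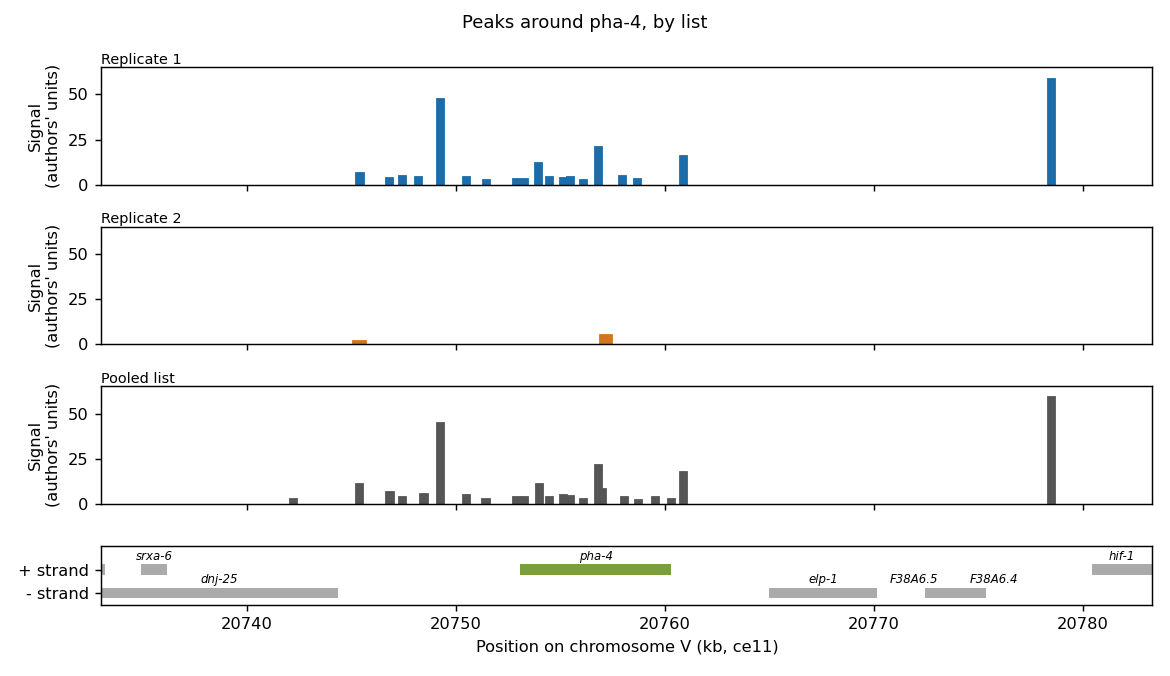
Peaks of replicate 1, replicate 2 and the pooled list around pha-4 on chromosome V (x axis, position in kb, ce11), drawn at their width with the authors' signal as bar height (y axis), above the protein-coding genes on each strand. Replicate 1 had 19 peaks in the 20 kb on either side and in the gene, replicate 2 had 2, and the tallest bars stand upstream of pha-4 and near hif-1.

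The region of pha-4 was dense in peaks in replicate 1 and in the pooled list. Within the gene and 20 kb on either side (V:20733052-20780317), the pooled list had 23 peaks, of which 9 were among its strongest 1000. Random placement gave a mean of 3.04 and 0.311 such peaks (p = 0.001 for both, one-sided permutation test, the smallest the placements can give). Replicate 1 had 19 peaks there, 6 of them in its top 1000 with ranks from 1. Replicate 2 had 2, against a random mean of 0.883 (p = 0.23, permutation test). Of these, V:20756892-20757481, in a pha-4 intron, ranked 6 in replicate 2 with a signal of 5.45, and it had 0 PHA-4 sites within 100 bp of its summit. Around unc-119, which is rescued in the strain, the pooled list had 3 peaks against a random mean of 3.79 (p = 0.73, permutation test) and none of the strongest 1000.

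The shared peak of best mean rank lay in that pha-4 intron. In replicate 1 it was V:20756654-20756997, ranked 8 with a signal of 21.2, with its summit at −84 bp from an internal transcript start of pha-4. It had 6 PHA-4 sites within 100 bp, and its summit sequence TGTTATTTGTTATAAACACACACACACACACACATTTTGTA holds ATAAACA. The summits of the replicates were 361 bp apart. Next among the shared peaks came ND5 and, on chromosome III at 13643542-13643885, the promoters of drr-2 and set-16, with signals of 14.04 in replicate 1 and 3.27 in replicate 2. Of the 15 shared peaks of best mean rank, 4 were mitochondrial, at ND5, at a tRNA gene next to COX2, and in ND1 and ND2. The others lay at promoters of rad-54.L2, C14A11.9, unc-60 with F53E2.2, the ribosomal protein gene rps-7, the protein disulfide isomerase gene pdi-3 and ZC506.1, in an intron of vav-1, and upstream of egl-27 and nud-2.

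Among the strongest 1000 peaks, 22 of replicate 2 (2.2%, 95% interval 1.38 to 3.31) overlapped 21 of replicate 1. Random placement gave a median of 11 and at most 21, a 1.95-fold excess (p = 0.001, one-sided permutation test, the smallest the placements can give). Without mitochondrial peaks 17 remained (permutation p = 0.01), and without these and the pha-4 region 16 (permutation p = 0.019). With windows of equal width in both replicates 13 were shared, and the excess was not past the threshold (fold 1.55, permutation p = 0.088). The excess was not kept when replicate 2 peaks were placed among promoter windows (permutation p = 0.18), when all peaks were used (fold 0.948) or when summits had to lie within 100 bp (1 shared peak, fold 0.409). The promoter placement put every replicate 2 peak in a promoter window, where 31.5% of replicate 2 summits lay, and raised the random median to 18. It therefore cannot show whether promoters account for the excess. Signals of the 21 shared peaks were not detectably related across peaks, which are not independent (rho = −0.0052, p = 0.98; r = 0.0743, p = 0.76; two-sided permutation tests). Pearson's r was 0.456 without mitochondrial peaks (permutation p = 0.071) and 0.2 with all peaks (permutation p = 0.056). Replicate 1 peaks of the strongest 1000 overlapped any replicate 2 peak in 2.9%, against 1.35% of the 4607 weaker ones (Fisher's exact p = 0.0012, two-sided). Without mitochondrial peaks and the pha-4 region the shares were 2.33% and 1.29% (Fisher's exact p = 0.019). The share did not follow rank evenly, with 1.33% at ranks 101 to 250, 4.8% at ranks 251 to 500 and 2.2% at ranks 501 to 1000. Of the rank groups only 251 to 500 passed the threshold against random placement (1.85%, permutation p = 0.003), and ranks 1 to 100 did not (4% against 1.965%, permutation p = 0.11). At ranks 3001 to 5607 the share, 0.997%, was below the 1.55% of random placements, so part of the contrast comes from the weakest peaks. By gene, 23 protein-coding genes had a peak in the promoter window in both replicates, among 664 in replicate 1 and 341 in replicate 2, where independent lists would share 11.3 (Fisher's exact p = 0.0012, two-sided). Without mitochondrial genes, a choice made after seeing the data, 17 were shared against 11.02, which did not pass (Fisher's exact p = 0.086).

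Peaks of replicate 1 sat in promoters more often than random placement, while the promoter share of replicate 2 did not differ detectably from random placement. In replicate 1, 52.6% of the strongest 1000 summits lay in a promoter window (95% interval 49.5 to 55.7) against 31.4% of random placements (p = 0.001, one-sided permutation test, the smallest possible). In replicate 2 the share was 31.5% (28.6 to 34.5) against 32.2% (permutation p = 0.69). The replicates differed by 21.1 percentage points (Fisher's exact p = 1.3e-21, two-sided). Coding exons held 2.6% of the replicate 1 summits and 34% of the replicate 2 summits (Fisher's exact p = 4.6e-84, two-sided), and 25.7% of random nuclear positions. Intergenic sequence held 56.1% and 27.8%, against 32.4% of random positions. Replicate 2 summits thus lay above random positions in coding exons and below them between genes. No test of either replicate against random positions was run for coding exons or intergenic sequence. Of the 21 shared peaks, 14 lay in promoter windows by their replicate 1 summits (66.7%, against 42.2% of random placements, p = 0.018, permutation test). Top replicate 1 peaks without a replicate 2 partner already had 52.3% there, so this gives no separate support for the shared peaks. Of the 9 final peaks, 5 lay in promoter windows (p = 0.22, permutation test). The shared result was not kept with the strongest 500 peaks (5 of 8, permutation p = 0.35).

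The PHA-4 consensus TRTTKRY was enriched at replicate 1 summits. It lay within 100 bp of 65.1% of the strongest 1000 summits of replicate 1 (95% interval 62.1 to 68.1) and in 47.1% of their flanks (exact sign-flip p = 6.6e-20, two-sided). In replicate 2 the shares were 48% (44.9 to 51.2) and 46.9% (p = 0.57), and the gain over flanks differed between replicates by 16.95 percentage points (permutation p = 1e-05, two-sided, the smallest the permutations can give). In replicate 1 the share was 70.4% at ranks 251 to 500, 60.2% at ranks 501 to 1000 and 51.9% at ranks 4001 to 5607. Among the 100 strongest peaks of replicate 2 the motif share was 59% against 49.5% in flanks (exact p = 0.099), and 40% of the summits lay in promoter windows (95% interval 30.3 to 50.3). The reversed pattern YRKTTRT shares the form TRTTTRT with the consensus, so it is not an independent control. It also exceeded its flanks in replicate 1, by less (50.7% against 43.9%, exact p = 0.00038). The GATA site WGATAR, bound by regulators of the intestine and epidermis, was depleted there (27.6% against 37.4%, exact p = 1.3e-07). The 21 shared peaks (61.9% against 50%, exact p = 0.46) and the 9 final peaks (6 with the motif, exact p = 0.38) did not differ detectably from their flanks. The final peaks near hif-1, upstream of pha-4 and at rpl-12 had no site within 100 bp of the summit.

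**Figure D2:**
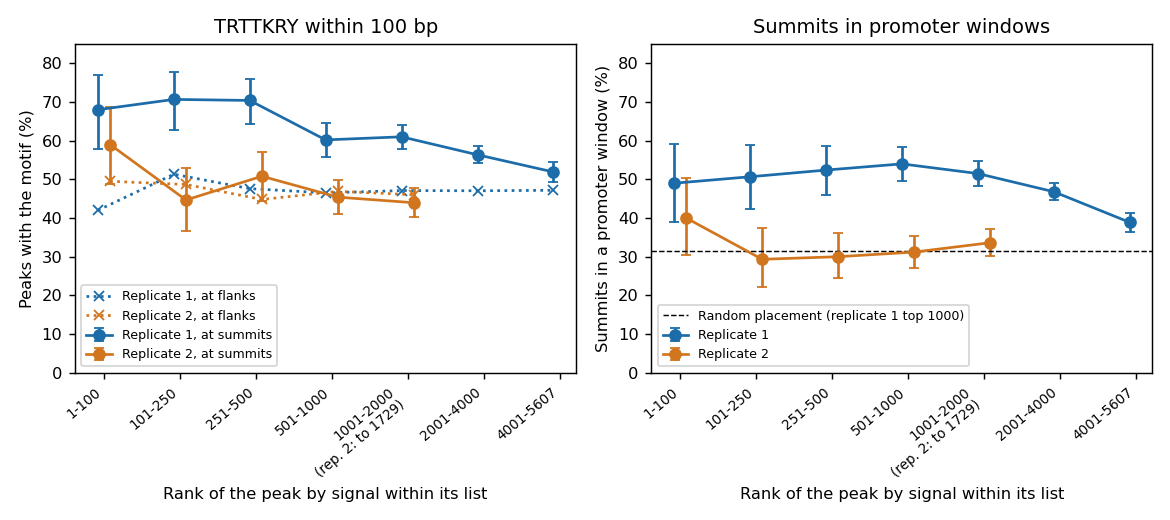
Share of peaks (y axes, percent) with the PHA-4 motif within 100 bp of the summit or at the flanks (left) and with the summit in a promoter window (right), by rank of the peak in its list (x axes), for both replicates. Bars are exact 95% intervals for the summits; replicate 1 lies above its flanks and above random placement, and replicate 2 lies near both except in its 100 strongest peaks, at 59% with the motif and 40% in promoters, with wide intervals.

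Among the 12 gene lists, the shared peaks favoured short RNA genes alone, through the mitochondrial genome. They marked 17 of 1131 short RNA genes against 10 of 25810 other genes that are not protein-coding (Fisher's exact adjusted p = 2.4e-16, two-sided), and with mitochondrial peaks and genes left out 1 member, R11A5.8, remained and no list passed. Among the other lists, pha-4 was the 1 of 27 pharynx genes with a shared peak (Fisher's exact adjusted p = 0.14, two-sided) and rps-7 the 1 of 76 ribosomal protein genes (exact adjusted p = 0.27). The other 9 lists had none.

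Tested by itself, replicate 1 marked ribosomal protein, short RNA, heat shock and histone genes more often than other genes. Of the 76 ribosomal protein genes, 21 had a summit in the promoter window (27.6%, 95% interval 17.99 to 39.1) against 3.2% of other protein-coding genes (Fisher's exact adjusted p = 1.7e-13, two-sided), among them rpl-3 (signal 20.4), rpl-12 (19.2) and rpl-13 (13.3). Of the nuclear short RNA genes, 84 of 1107 had one, made up of 37 of 346 snoRNA, 43 of 612 tRNA, 4 of 129 snRNA and 0 of 20 rRNA genes. The share was 7.59%, against 2.04% of other genes that are not protein-coding (Fisher's exact adjusted p = 2.1e-21, and 0.006 against random placement). That background lies below the 3.2% of the protein-coding comparison, so the exact test depends on the class chosen. Heat shock genes had 4 of 16 (hsp-1, hsp-3, hsp-16.2 and hsp-16.41, from 3 peaks, exact adjusted p = 0.0062) and histone genes 7 of 72 (from 4 peaks, exact adjusted p = 0.028). The heat shock call was lost with all replicate 1 peaks (6 of 16, exact adjusted p = 0.054, and 0.017 against random placement) and with the nearest transcript start (0.075). The histone call was lost with the strongest 500 (exact adjusted p = 0.27), all peaks (0.07, and 0.008 against random placement), the nearest start (0.75) and the pooled list (0.22). The autophagy genes atg-7, epg-8 and lgg-2 made 3 of 22 (exact adjusted p = 0.082, and 0.036 against random placement). This list passed with 500 bp upstream (3 of 22, exact adjusted p = 0.042), with 2000 bp upstream (6 of 22, 0.0012) and with the nearest start (5 of 22, 0.0092). Pharynx genes had 2 of 27, ceh-22 with a signal of 10.8 and pha-4 (exact adjusted p = 0.38), epidermis genes 2 of 22 (ajm-1 and vab-10), body muscle genes 1 of 21 (act-4), and intestine, neuron, germline and antioxidant genes none. With all replicate 1 peaks, 9 of 27 pharynx genes had one, avr-15, ceh-22, hlh-6, mlc-2, myo-1, myo-2, peb-1, pha-4 and tbx-2 (33.3% against 14.3% of other genes, exact adjusted p = 0.041). Body muscle genes had the same share, 7 of 21 (exact adjusted p = 0.054, and 0.017 against random placement), and autophagy genes 7 of 22 (0.058 and 0.014). Random placement ignores the general preference of replicate 1 peaks for promoters (46.4% of all its summits against 31.6% of random placements). A pass against it alone therefore does not single out a list. With all replicate 1 peaks, 7 of the 12 lists passed against random placement and 3 by the exact test.

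Tested by itself, replicate 2 marked pharynx and germline genes more often than other genes. By the authors' q-values its peaks are not told apart from background, since the smallest q in replicate 2 was 0.351. Its promoter and motif shares also did not differ detectably from random placement and flanks. The genes named here are therefore not shown to be targets of PHA-4. The pharynx regulators ceh-22, peb-1, pha-4 and tbx-2 made 4 of 27 (14.8% against 1.66% of other genes, Fisher's exact adjusted p = 0.006, two-sided, and 0.042 against random placement), with tbx-2 at a signal of 3.5. At ceh-22, peb-1 and tbx-2 the nearest summits of the 2 replicates were 1294, 824 and 526 bp apart, and their peaks did not overlap. The germline genes gld-1, him-3, mex-5, pgl-1 and rec-8 made 5 of 15 (exact adjusted p = 4e-05, and 0.012 against random placement). They came from 3 peaks, and none of these genes had a peak in replicate 1. With the strongest 500 peaks the pharynx list was not past the threshold (2 of 27, exact adjusted p = 0.13), nor with all peaks (4 of 27, 0.052). With each summit given to its nearest transcript start, neither list was (exact adjusted p = 0.1 for both). Whether the replicates differ in any list was not tested. Of the remaining lists, ribosomal protein genes had 3 of 76 (rps-7, rps-21 and rps-23), short RNA genes 19 of 1107, epidermis genes 1 of 22 (bli-1), neuron genes 1 of 25 (unc-119), and the others none.

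**Figure D3:**
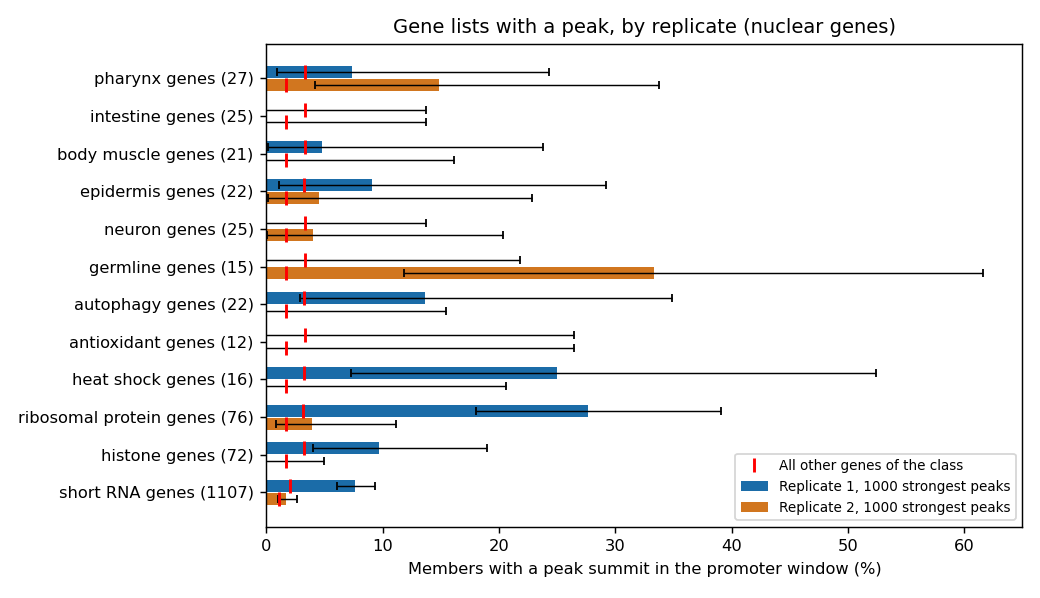
Share of the nuclear members of each gene list (number in brackets) with a summit of the 1000 strongest peaks in the promoter window (x axis, percent) for each replicate, with exact 95% intervals. Red ticks mark all other genes of the class in the same replicate; ribosomal protein genes reach 27.6% in replicate 1, and germline genes 33.3% in replicate 2.

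On the X chromosome, which makes up 17.7% of the genome, lay 23.5% of the strongest 1000 peaks of replicate 1 (95% interval 20.9 to 26.3) and 20.3% of those of replicate 2 (17.9 to 22.9). The mitochondrial genome held 5 and 6 of them, though it makes up 0.01375% of the genome. Whether the mitochondrial peaks reflect binding was not tested.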

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

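Tests on nuclear lists per replicate, random placement of list members, the equal-width overlap and results without mitochondrial peaks were chosen after seeing the data. Of 141 alternative values, 101 were classed as the same, 15 as weaker, 6 as stronger, 9 as reversed and 10 as moved. For values with a test, the same means that direction and side of the threshold were kept. Counts and shares without a test have no threshold, and those classed as the same could still change. For example, the 4 lists passing in replicate 1 became 3 with the strongest 500 and 5 with 500 bp upstream. Unless stated, the cause of a change was not tested. The ce10 build gave 21 final peaks in place of 9, but the number of control alignments differed too (1 in ce10, 2 in ce11), so build and controls are not separated. The 1.95-fold replicate overlap became 1.99 with the strongest 500 (permutation p = 0.052, fewer peaks), 0.948 with all peaks, 1.19 with a reciprocal overlap of 50%, 0.409 with summits within 100 bp, 1.23 among promoter windows and 1.55 with equal widths. The placement among promoter windows put every replicate 2 peak at a promoter, so it cannot show whether promoters account for the excess. The overlap stayed past the threshold in ce10 (1.81), without mitochondrial peaks (1.85) and without these and the pha-4 region (1.75). The rank correlation, near 0, was 0.524 with the strongest 500 (8 peaks), 0.0398 with all peaks and 0.12 in ce10, never past the threshold. With summits within 100 bp, 0% of final peaks were found in replicate 2. The promoter share of shared peaks was 62.5% with the strongest 500, and 31.5 to 52.6% with a single replicate; the lower end is replicate 2 and lies below random placement. The replicate 2 promoter share crossed to just above random placement with 500 bp upstream (23.7%) and with all peaks (32.4%). The number of lists passing, 1 with shared peaks, was 2 with all peaks, 3 with the pooled list, 0 without mitochondrial peaks, and 3 to 4 with a single replicate. For replicate 2, 2 lists became 1 with the strongest 500 and with all peaks, in both cases the germline list. With the nearest start 1 list passed, which was neither the pharynx nor the germline list. With a single replicate in place of the shared peaks, the motif gain was 1.1 to 18.05 percentage points. The upper value is replicate 1 and past the threshold. In replicate 2 the gain was −0.25 with 250 bp on each side. Replicate 1 kept its promoter call in all 4 alternatives and its motif call in all 4 that used the PHA-4 pattern. The reversed pattern also passed (6.8 percentage points, exact p = 0.00038). It shares the form TRTTTRT with the consensus, so this pass cannot show whether the gain is particular to the PHA-4 pattern. The ribosomal protein and short RNA lists of replicate 1 kept the call in all 7 each. Its histone list lost the call in 4 of 7 and its heat shock list in 2, while its autophagy list gained it in 4 and its pharynx list in 1. The autophagy gains include random placement, which ignores the general promoter preference of replicate 1 peaks. In replicate 2 the pharynx list lost the call in 3 of 6 and the germline list in 1. A stricter score could not be run because the score is 0 throughout, and the rank correlation with summits within 100 bp had 1 peak and no value. No paired analysis was possible because there is 1 group. Depth is unknown, so weak enrichment in replicate 2 cannot be set against its number of reads.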

Other observations

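The gene family tests, the tests of differences between replicates, the per-peak split of the repeat measure and the comparison of strong with weaker peaks were chosen only after the data were seen. Over the 175 families defined by symbol stem, tested in each replicate, replicate 1 marked the large and small ribosomal subunit families rpl (13 of 47, Fisher's exact adjusted p = 4.1e-07, two-sided) and rps (9 of 31, adjusted p = 3.9e-05). It also marked rpb-3, rpb-6, rpb-10 and rpb-11, subunits of RNA polymerase II (4 of 11, exact adjusted p = 0.019), and the cytochrome c oxidase genes cox-5B, cox-6B, cox-6C and cox-14 (4 of 15, exact adjusted p = 0.041). Chemoreceptor genes of the srh family were marked less often than other genes (0 of 220 against 3.33%, exact adjusted p = 0.041). In replicate 2 the unc family, which groups genes by a movement phenotype and not by sequence, had 8 of 94 (exact adjusted p = 0.032).

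In the replicate 1 list, peaks at ribosomal protein and short RNA genes differed from the rest in sequence. Of 90 such peaks, 42.2% held the PHA-4 motif within 100 bp and 45.6% of their flanks did (exact sign-flip p = 0.7, two-sided), against 67.2% of the other top peaks (Fisher's exact p = 4.5e-06, two-sided). Crowding of genes that share windows was argued against, since 21 ribosomal protein genes had a peak where the highest of 1000 random placements was 6, and 84 short RNA genes where it was 33. A candidate explanation is signal without the consensus site at strongly transcribed genes, through PHA-4 or independent of it; transcription was not measured and no other immunoprecipitation was analysed here.

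For the weak replicate 2, a role of its wider windows cannot be told apart, since an equal width moved the share of shared top peaks from 2.2% to 1.3% but narrowing a window can only lower it. A different target or sample remains open, since 9 of the 100 strongest replicate 2 peaks overlapped a replicate 1 peak, within the 95th percentile of random placements (12). Between the strongest 1000 of each replicate, 22 replicate 2 peaks overlapped, against at most 21 by random placement (permutation p = 0.001). That excess was not kept in several other settings, such as equal widths (permutation p = 0.088). Low enrichment also remains open, with a promoter share of 31.5% against 52.6% and strong replicate 1 peaks found more often than weaker ones (2.9% against 1.35%, or 2.33% against 1.29% without mitochondrial peaks and the pha-4 region), though unevenly by rank, with only ranks 251 to 500 past the threshold against random placement (4.8% against 1.85%) and ranks 3001 to 5607 below it (0.997% against 1.55%). The pha-4 intron peak at rank 6 may point to weak enrichment of the same factor, but it is a single peak with 0 PHA-4 sites within 100 bp of its summit, and the motif gain of the 100 strongest replicate 2 peaks did not pass (9.5 percentage points, exact p = 0.099). The peak also lies at pha-4, where extra copies of the transgene DNA are not told apart from binding. Within 20 kb of pha-4 replicate 2 had 2 peaks against a random mean of 0.883 (permutation p = 0.23). No biological explanation was tested, since the replicates belong to 1 group.

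For the peaks near pha-4, reads from repeat copies were argued against for the peak upstream of pha-4, with 5.14% of its bases masked as repeats, and cannot be told apart for the peak near hif-1, with 30.3%, between the bounds of 20% and 50% set for the test. Extra copies of the transgene DNA also cannot be told apart from binding. Outside the gene and its upstream 5 kb, 6 pooled summits stood against a 95th percentile of 5 (permutation p = 0.03, one-sided), as extra copies could give. Within 20 kb of unc-119 there were 3 against 7. How much of that region the transgene carries is not known here, so this count might not rise with extra copies and does not argue against them. In the unc-119 gene itself the pooled list had 2 peaks against a random mean of 0.528 (permutation p = 0.1). Downstream of pha-4 a stretch of 17614 bp, across elp-1, had no summit before the peak near hif-1. Binding of PHA-4 to its own locus stays open and was not separated from copy number.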
